A study of Caenorhabditis elegans with 2 samples.

How the data were processed

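Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of UNC-30 was carried out on whole Caenorhabditis elegans larvae of the L1 stage, of both sexes mixed, from 1 transgenic strain. Per the labels, the strain carries an integrated transgene, wgIs395, that expresses UNC-30 with a GFP-FLAG tag at its C terminus, in a background with a mutation of unc-119. The chromatin was fragmented by sonication with a microtip, per the labels, and the extraction protocol is not given there. There are 2 libraries in 1 group, which the labels name as biological replicates 1 and 2. No second condition, stage or strain was analysed here, so no comparison between groups exists. All tests below compare sets of genomic regions or genes within this group, and their p-values describe these 2 libraries, not a spread over many animals.

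Per the file lists that accompany the samples, the authors deposited for each replicate a list of candidate regions (true peaks together with background) made from that replicate's alignments and 1 further file. They also deposited a candidate list made from both replicates together, and a list of peaks thresholded by the irreproducible discovery rate (IDR) from the other lists. Each list exists for the genome builds ce11 and ce10. The aligner, the peak caller and its settings, the nature of the control and the IDR threshold are not given in the sources used here. Each region in the deposited lists carries a signal value, which is the authors' own measure of peak height, with a scale that the sources used here do not give. It was used to rank, filter and average regions within a list, and across lists only where replicate 2's mitochondrial regions are set against the pooled list. Each region also carries a −log10 q-value and the offset of its summit, as the narrowPeak format of the deposited lists defines them. The thresholded lists were found to repeat the pooled lists' −log10 q-values, so no IDR per peak was at hand.

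Each candidate list holds 30000 regions. All 125 thresholded ce11 peaks equal the top of the pooled list by signal value, as do all 103 thresholded ce10 peaks. In ce11 the thresholded peaks are 356 bp wide, and 52 of them share the highest −log10 q of 2.01. The median −log10 q is 1.38 and the lowest 0.668, a q-value above 0.05, so by this value the lower peaks are less certain. Among the 125 peaks, 2 pairs of neighbours share bases, which leaves 123 separate loci. Read counts are in none of the lists, so the depth of each library is unknown. Intervals of shares are 95% Wilson intervals over regions and cover counting error only.

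The ce11 lists were used for all main values, with the ce11 (WBcel235) genome sequence and the gene annotation of Ensembl release 115, which holds 19985 protein-coding genes. All ce11 regions lie within the chromosome lengths of that sequence. The ce10 lists were used for counts and overlaps alone, because no ce10 sequence or annotation was used here, and no coordinate was converted between builds. Coordinates count from 1.

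Replicates were compared through the 125 highest-signal regions of each replicate's own list. A region was called shared when the summits lay within 100 bp, and chance overlap came from 10000 circular shifts along the chromosomes (one-sided permutation test). A promoter was the span from 2000 bp upstream to 500 bp downstream of the annotated 5′ end of a protein-coding gene. Locations, promoters and chromosomes of the thresholded peaks were compared with those of the 29857 pooled candidate regions away from any thresholded peak, by Fisher's exact test (two-sided). TAATCC, the core sequence bound by homeodomains of the bicoid type to which UNC-30 belongs, was searched on both strands within 100 bp of each summit. Background windows of the same width, 201 bp, lay 1000 bp to each side, without those touching a peak window. The dependence on rank was tested between the upper and lower parts of the peaks by signal, with 100000 random permutations (two-sided). All 2080 pairs of a 6-mer and its reverse complement were tested in the same windows. Adjusted p-values are Benjamini-Hochberg values over the 6-mers, over the 6 nuclear chromosomes, over the 5 kinds of location or over the 15 gene lists.

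Before the data were examined, 15 gene lists were fixed: GABA identity, GABA receptors, D-type motor neuron genes, cholinergic motor neuron identity, other transmitter identities, pan-neuronal genes, neuropeptides, acetylcholine receptors, axon guidance and synapse, homeobox genes, body wall muscle, hypodermis, intestine, ribosomal proteins and histones. Every gene symbol written into them was found in the annotation. A list's genes with a promoter peak were compared with all other protein-coding genes by Fisher's exact test. The rule for named genes, also fixed before, took the nearest protein-coding gene of the 20 highest-signal peaks and 4 genes whatever their values (unc-30, unc-25, unc-47 and unc-119). It further took up to 6 members with a promoter peak from each list and the 5 highest-signal peaks with TAATCC. Some genes outside this rule are named as well, among them cyc-2.1 and hsp-60, whose promoters hold peaks of the 20 highest.

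The alternatives fixed before were ce10 in place of ce11, a stricter and a looser peak list, other overlap distances (50 and 200 bp or any shared base), other promoter windows, other motif windows and backgrounds, and each replicate's own list in place of the thresholded peaks. Alternatives added after seeing the data were the 500 and 1000 highest-signal pooled regions, the peaks found near the top regions of both replicates, replicate 2's list without its mitochondrial regions, and whole candidate lists for replicate support. The overlap, motif, 6-mer, gene list, promoter and rank tests were tested on simulated data first. With TAATCC added to 40 of 125 simulated windows, it ranked 1 among the 2080 6-mers, and with none added, 0 6-mers passed the threshold. Both simulated sets came from flanking sequence. A difference in G+C content between peaks and flanks was therefore not covered, nor was a motif excess as small as that found below. All 50 summits placed upstream of a gene were assigned to that gene. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.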

Results

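UNC-30 is a homeodomain transcription factor of the Pitx family that specifies the GABAergic D-type motor neurons of C. elegans, where it activates unc-25 (glutamic acid decarboxylase) and unc-47 (the vesicular GABA transporter). ChIP-seq against it in L1 larvae gave 2 libraries, biological replicates 1 and 2, of a strain with a tagged UNC-30 transgene. Whole larvae were used, so the cells that express UNC-30 are a small part of each sample. The question such an experiment addresses is where in the genome the protein is found. The authors' list of peaks that passed their reproducibility threshold held 125 peaks in the ce11 build and 103 in ce10. Signal values, the authors' measure of peak height, ran from 39.2 to 113 with a median of 49.3 over the ce11 peaks. The pooled candidate list of 30000 regions reached down to a signal of 10.7. Library depths are unknown, and all coordinates are ce11.

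The strongest peaks included sites on chromosome X away from gene starts and promoters of ribosomal protein genes. The highest, with a signal of 113, covered positions 11093946 to 11094301 of chromosome X, an intergenic site 4062 bp downstream of the 5′ end of W02H3.3. The peak of rank 2 (signal 110, chromosome II, 10563381 to 10563736) had its summit 152 bp upstream of cdc-48.1, which encodes a AAA-type ATPase that extracts ubiquitinated proteins. Further peaks on X among the 20 highest had as nearest genes Y41G9A.17 (signal 103, in an intron, 2996949 to 2997304), cest-16 (94.1, in an intron, 6296357 to 6296712), ZK899.6 (86.4), xol-1 (82.0), nspc-17 (80.5) and T03G6.1 (75.5). xol-1, the switch gene of sex determination, had the peak 4928 bp upstream of its 5′ end. In total 7 of the 20 highest peaks were on X.

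Promoter sites made up a second set among the 20 highest. The summit near rpl-3, which encodes a protein of the large ribosomal subunit, lay 260 bp upstream (signal 90.0, chromosome III, 3867416 to 3867771). That near rps-1, of the small subunit, lay 237 bp upstream (78.0, chromosome III, 4475503 to 4475858). The peak whose nearest gene was Y17G9B.5 (80.7) also lay in the promoters of rpl-20 and of cyc-2.1, a cytochrome c gene. The peak nearest to Y22D7AL.10 (78.3) lay in the promoter of hsp-60 as well, which encodes the mitochondrial chaperonin. dld-1, which encodes dihydrolipoamide dehydrogenase, had its summit 200 bp upstream (75.8), and cdk-5, a kinase gene with roles in neurons, 65 bp upstream (75.0). Y87G2A.18 (89.4) and eelo-2 (73.2) also had summits within 500 bp upstream. The remaining nearest genes were W06H8.6 (98.2), Y111B2A.12 (93.3), nlp-40 (88.8) and znf-782 (79.9), with summits 2387 to 5548 bp from the 5′ end. In all, 10 of the 20 summits lay over 2000 bp from the nearest 5′ end and 9 lay 1 to 500 bp upstream of it.

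The replicates shared part of their strongest regions. Of the 125 highest regions of replicate 1, 29 had a summit of replicate 2's 125 highest within 100 bp, or 23.2% (95% interval 16.7 to 31.3). Shifted sets shared 0.026% on average (one-sided permutation p = 1e-04, the smallest that 10000 shifts can give). The share fell with depth, from 35.5% of the 62 highest regions to 16.8% of the 250 highest and 8.2% of the 1000 highest, the last a depth chosen after seeing the data. Of the thresholded peaks, 90 (72.0%) matched a top region of replicate 1 and 44 (35.2%) a top region of replicate 2. Both replicates matched at 33 peaks (26.4%, interval 19.5 to 34.7), among them those near W02H3.3, cdc-48.1, rpl-3, rps-1 and nlp-40. Replicate 1 alone matched at 57 peaks and replicate 2 alone at 11 (exact binomial test over peaks, two-sided, p = 1.28e-08), a comparison of these 2 libraries alone. Of replicate 2's 125 top regions, 10 are mitochondrial and can match no peak. With its 125 highest nuclear regions, chosen after seeing the data, the counts were 56 and 12 (same exact test, p = 6.21e-08). Neither matched at 24 peaks. The match rose with the whole candidate lists, which hold background as well: 102 peaks (81.6%) then had a region in both.

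**Figure D1:**
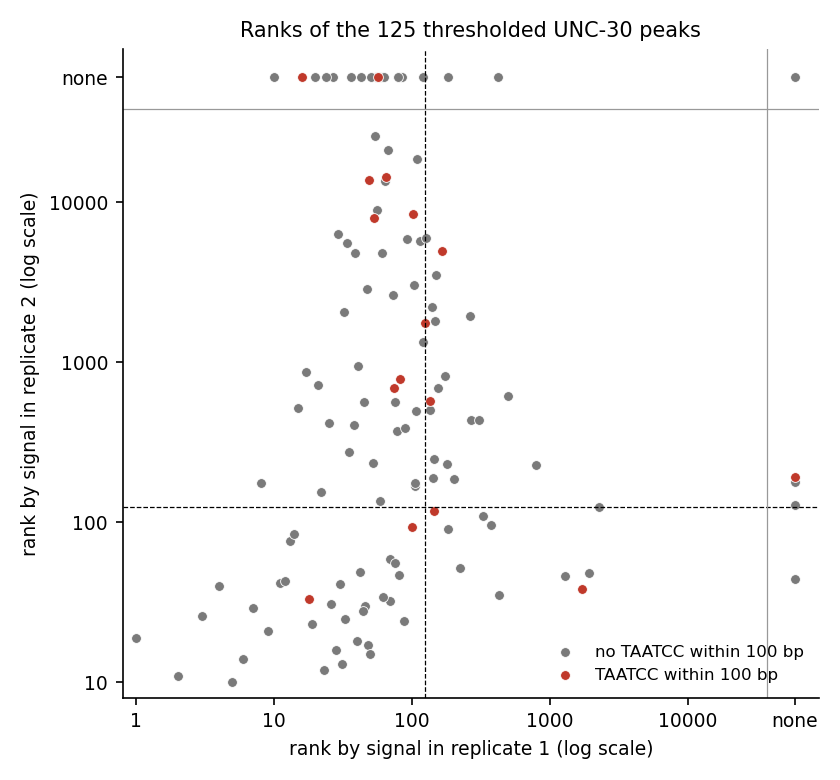
Rank by signal value of each of the 125 thresholded peaks in the candidate list of replicate 1 (horizontal, log scale) and of replicate 2 (vertical, log scale), with "none" for a peak without a summit within 100 bp in that list and dashed lines at rank 125. Red points hold TAATCC within 100 bp of the summit, and 90 peaks rank within the top 125 of replicate 1 against 44 in replicate 2.

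Thresholded peaks lay between genes and close upstream of gene starts more often than the other candidate regions. Intergenic summits made up 78.4% of the peaks (interval 70.4 to 84.7) and 42.9% of the other candidates (odds ratio 4.84, Fisher's exact test, adjusted p = 4.07e-15). Introns held 13.6% against 38.5% (adjusted p = 3.64e-09) and coding exons 1.6% against 12.96% (adjusted p = 1.88e-05, same exact test). 5′ UTRs held 4.8% against 1.52% (adjusted p = 0.0159), while 3′ UTRs, at 1.6% against 4.20%, did not differ by this exact test (adjusted p = 0.18). Promoters held 78 peaks, or 62.4% (interval 53.7 to 70.4), against 42.1% of the other candidates (odds ratio 2.29, Fisher's exact test, p = 6.61e-06). The window from 1 to 500 bp upstream held 56 peaks (44.8%), against 11.2% (odds ratio 6.42, Fisher's exact test, p = 4.28e-21). Of the 33 peaks that matched both replicates, 48.5% lay in promoters, a difference from the other candidates that did not pass the exact test (p = 0.48).

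**Figure D2:**
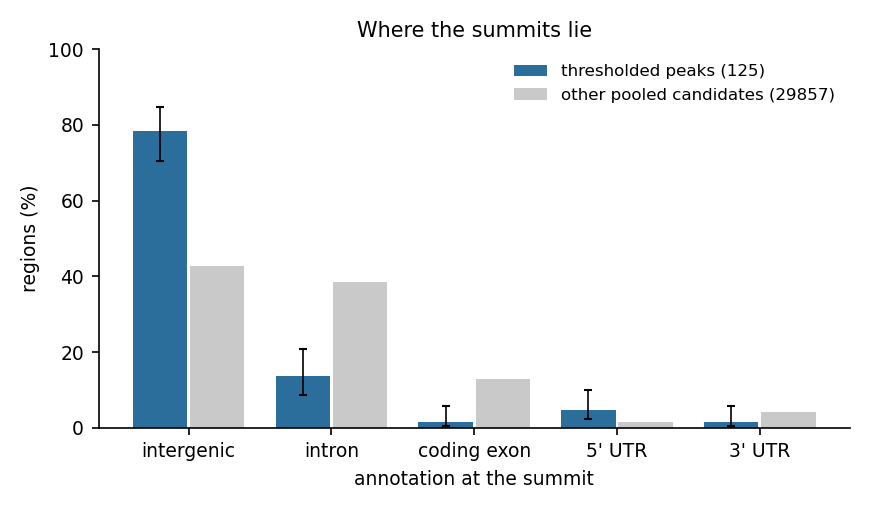
Share of summits (vertical, %) at each kind of annotation (horizontal) for the 125 thresholded peaks (blue, with 95% Wilson intervals) and the 29857 other pooled candidate regions (grey). Intergenic summits make up 78.4% of the peaks against 42.9% of the other candidates, and introns 13.6% against 38.5%.

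The chromosomes held thresholded peaks in about the shares of the other candidate regions. X held 22 of the 125 peaks, or 17.6% (interval 11.9 to 25.2), against 17.8% of the other candidates (odds ratio 0.989, Fisher's exact test, adjusted p = 1). Chromosome I held 19.2% against 15.7%, II 16.0% against 12.9%, III 16.8% against 14.9%, IV 15.2% against 19.9% and V 15.2% against 18.8%. No chromosome passed the threshold (Fisher's exact test, lowest unadjusted p = 0.217, lowest adjusted p = 0.538). With replicate 1's own 125 highest regions in place of the peaks, V fell short, at 8.8% against 18.9% (exact test, adjusted p = 0.0162).

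TAATCC was present within 100 bp of 16 of the 125 summits, or 12.8% (interval 8.03 to 19.8), and in 18 of 248 flanking windows, or 7.26% (interval 4.64 to 11.2). The odds ratio was 1.88 and the difference did not pass the test (Fisher's exact test, p = 0.0881). The 5 highest-signal peaks with the motif had T03G6.1, F47F2.3, msp-55, nspb-12 and unc-60 as nearest genes, and none of the 5 lay in a promoter. The peak near T03G6.1 (chromosome X, 2604622 to 2604977, signal 75.5, in a coding exon) held TAATCC at 2604811 to 2604816 on the plus strand, in the sequence TGCTCTTCCATAATCCAGGTAGGATT. Near F47F2.3 (X, 3898451 to 3898806, signal 58.1) the motif was at 3898666 to 3898671, in GGACCATTCATAATCCTTGCACAAAG, and that peak had no region in replicate 2's list. The peaks near msp-55 (IV, 5054312 to 5054667), which belongs to the major sperm protein family, and nspb-12 (III, 5571100 to 5571455) had signals of 57.5 and 51.4. That near msp-55 had no region in replicate 1's list, and that near nspb-12 ranked 1729 there. The peak near unc-60 (V, 1471642 to 1471997, signal 50.02), the gene of an actin depolymerizing factor, lay 3266 bp upstream of the 5′ end.

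The motif's share depended on the window, the depth of the list and the replicate. Within 50 bp of the summit it was 10.4% against 3.2% in the flanks (exact test, p = 0.00734). Within 200 bp it was 18.4% against 11.7%, which did not pass (exact test, p = 0.0833). The shorter motif TAATC, within 100 bp, did not differ either, at 36% against 34.3% (exact test, p = 0.818). Over the 500 highest-signal pooled regions, a set chosen after seeing the data, the share with TAATCC was 14.2% against 7.27% (odds ratio 2.11, exact test, p = 3.56e-05). The top 500 nuclear regions of replicate 1 held the motif in 13.8% and those of replicate 2 in 7.8%, also compared after seeing the data (Fisher's exact test, p = 0.00299). Over the top 125 nuclear regions the shares were 13.6% and 7.2%, which did not pass the exact test (p = 0.146). Against their own flanks, replicate 1's top 125 regions stood at 13.6% against 7.32% (exact test, p = 0.0604). Replicate 2's had no excess, at 6.96% in its 115 nuclear windows and in their flanks. Within the thresholded peaks, 5 of the 62 with the higher signal held it (8.06%) and 11 of the other 63 (17.5%). This difference of -9.40 percentage points did not pass the permutation test (p = 0.188).

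**Figure D3:**
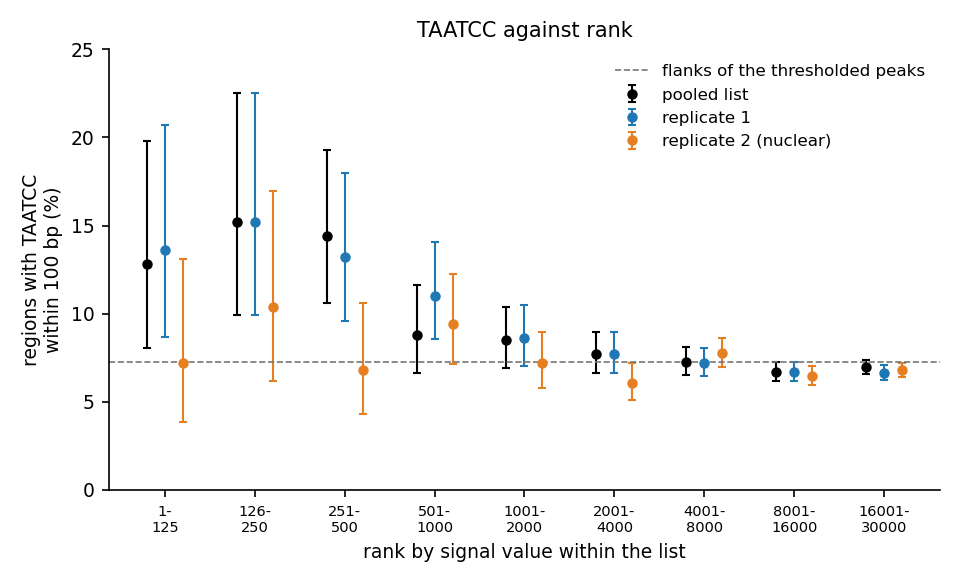
Share of regions with TAATCC within 100 bp of the summit (vertical, %, with 95% Wilson intervals) against rank by signal value (horizontal, bins of rank) in the pooled list, replicate 1 and the nuclear regions of replicate 2. The pooled share is 12.8%, 15.2% and 14.4% in the bins down to rank 500 and 8.8% from rank 501 to 1000, and the dashed line marks the 7.26% of the flanks of the thresholded peaks.

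Other sequences set the summits apart more strongly than TAATCC. Of the 2080 6-mers, 63 were more frequent in peaks than in flanks and 7 less frequent (Fisher's exact test, Benjamini-Hochberg). ATGCGC was in 23 of 125 peaks and 0 of 248 flanking windows (exact test, adjusted p = 5.77e-09), GACGCA in 29 peaks and 5 flanking windows (9.10e-08), CGCGCA in 26 and 7 (2.07e-05) and ACGCAG in 29 and 10 (2.09e-05). ATGCGC was in 0 of the 22 peaks on X and 23 of the 103 autosomal peaks. GACGCA (1 on X, 28 autosomal) and ACGCAG (2 and 27) were also mainly autosomal. CGCGCA went the other way, in 10 of the 22 X peaks and 16 of the 103 autosomal peaks. Of these X peaks, 8 also held CGCAGGGA, a sequence taken up under the other observations. TAATCC ranked 374 by the same exact test (adjusted p = 0.488). The median G+C content was 38.8% in peak windows, 35.8% in flanks and 31.8% in the other candidates. Against candidates of matched G+C content 47 6-mers were more frequent. The contrasts were smaller for the 6-mers named above, but not for AGCGCG, the first by p in that setting (odds ratio 7.19, and 7.13 against flanks). ATGCGC was then in 18.4% of peaks and 4.96% of the matched regions (odds ratio 4.32), and the odds ratio was 4.54 for GACGCA (14.7 against flanks), 5.50 for CGCGCA (9.04) and 3.89 for ACGCAG (7.19). With each replicate's own top regions in place of the peaks, the count was 84 for replicate 1 and 2 for replicate 2.

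Among the 15 gene lists, only ribosomal protein genes passed the test. Of 79 such genes, 7 (8.86%) had a peak in the promoter, against 0.638% of the other protein-coding genes (odds ratio 15.1, Fisher's exact test, adjusted p = 1.51e-05). The 7 genes were rpl-3, rpl-20, rps-1, rps-20 (signal 66.0), rpl-35 (61.1), rps-28 (44.3) and rps-12 (43.4), the last beyond the limit of 6 and named because it completes the count. The summits lay 170 to 571 bp upstream of the 5′ ends, and none of the 7 peaks held TAATCC. rps-28 had no region in replicate 1's list. With each peak given to its nearest 5′ end only, 4 of the 79 genes had one (odds ratio 8.94, Fisher's exact test, adjusted p = 0.0209). Of 95 homeobox genes, ceh-38, a gene of the ONECUT class, was the member with a promoter peak (signal 50.4, chromosome II, 6951399 to 6951754, 51 bp downstream of the 5′ end, in the 5′ UTR). Its list did not pass the exact test (p = 0.473 unadjusted, adjusted p = 1). In all, 134 protein-coding genes had a thresholded promoter peak, and 43 of the 78 promoter peaks lay in the promoters of 2 or more genes.

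None of the lists tied to neurons or to the other tissues of the animal had a member with a thresholded promoter peak. This held for GABA identity (5 genes), GABA receptors (9), D-type motor neuron genes (10), cholinergic motor neuron identity (14), other transmitter identities (10), pan-neuronal genes (26), neuropeptides (102), acetylcholine receptors (30), and axon guidance and synapse (30). It also held for body wall muscle (23), hypodermis (21), intestine (20) and histones (72). Each gave p = 1 unadjusted in Fisher's exact test, and the counts could not have passed it in lists of this size. Random draws of 125 candidate regions gave on average 0.0164 GABA identity genes, 0.0348 D-type genes and 0.383 neuropeptide genes. Among the 1000 highest-signal pooled regions, chosen after seeing the data, 27 ribosomal protein genes had a promoter region. So did ttr-39 of the D-type list (signal 27.2), the pan-neuronal genes unc-64 (syntaxin, 34.5) and snn-1 (synapsin, 26.9), the neuropeptide genes nlp-12 and flp-19, unc-53 of the axon guidance list, ceh-38 and dve-1 of the homeobox list, unc-45 of body wall muscle and his-72 of the histones. Of D-type genes 10% had one (against 3.97% of other genes), of pan-neuronal genes 7.69% (against 3.97%) and of body wall muscle genes 4.35% (against 3.97%). The shares of neuropeptide genes (1.96% against 3.98% of other genes), axon guidance genes (3.33% against 3.97%), homeobox genes (2.11% against 3.98%) and histones (1.39% against 3.98%) were below those of other genes. No list other than ribosomal proteins passed there either.

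The known targets of UNC-30 lay below the threshold or outside the candidate lists. At unc-25 (chromosome III, 12942651 to 12949883, plus strand) a candidate from 12942358 to 12942713 had its summit at 12942536, just upstream of the 5′ end. It ranked 1707 in the pooled list (signal 23.1) and 468 in replicate 1 (18.9), and replicate 2's list had no promoter region there. It held TAATCC on the plus strand at 12942594 to 12942599, in TGAGCCACAGTAATCCTTGGGGGCGG, and on the minus strand at 12942544 to 12942549, in TTGCTCATTGGGATTATAGTCACGCC. unc-47 (III, 10183762 to 10186260) had no candidate in its promoter or within 2000 bp of the gene in the pooled list or either replicate's. The strain's rescue marker, unc-119 (III, 10902641 to 10908935), had its highest candidate within 2000 bp of the gene at 10903473, with a signal of 33.5 and rank 229 in the pooled list. unc-30 itself (IV, 13118977 to 13124406) had no candidate in its promoter or within 2000 bp in any of the 3 lists. The nearest pooled candidates lay beyond a gap from 13091917 to 13143243.

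**Figure D4:**
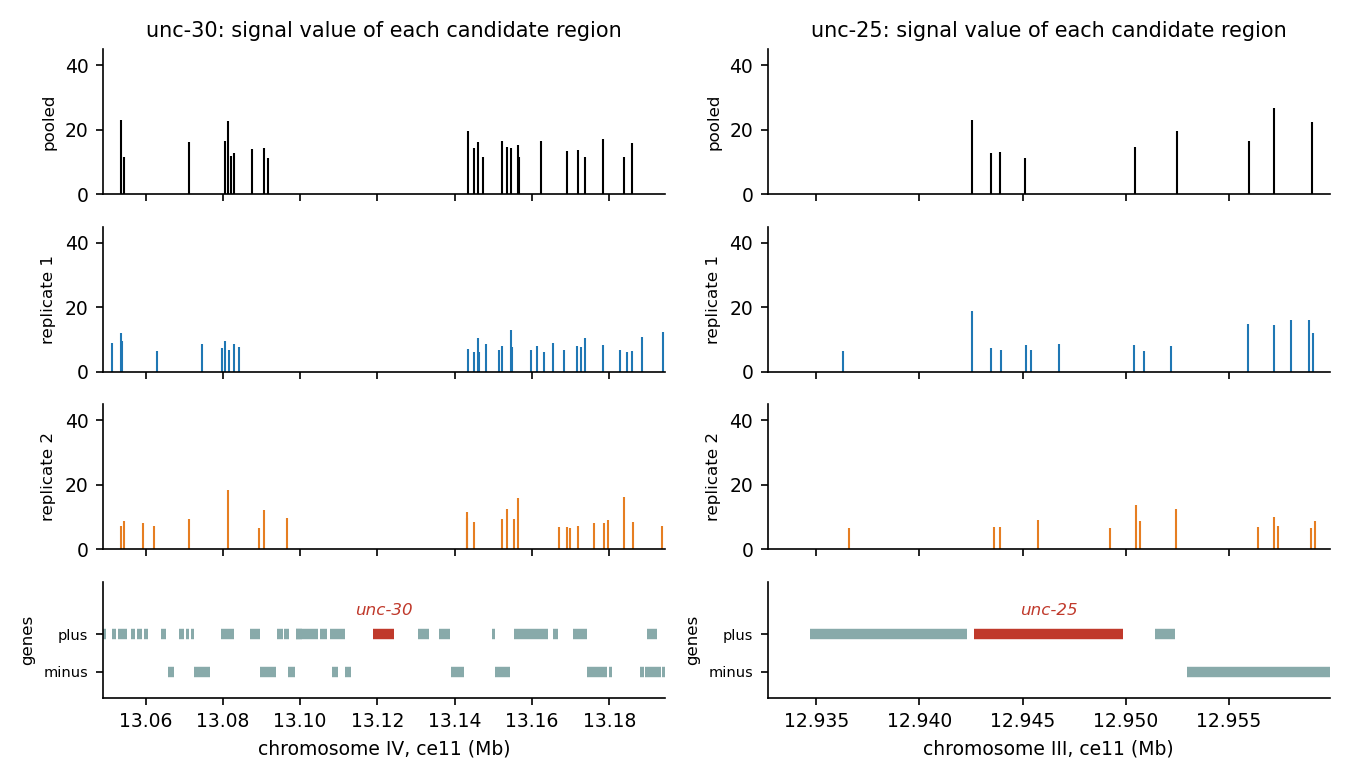
Candidate regions around unc-30 (left, chromosome IV) and unc-25 (right, chromosome III), with position (horizontal, Mb, ce11) and signal value (vertical, authors' unit) in the pooled list, replicate 1 and replicate 2, and protein-coding genes by strand at the bottom. No candidate lies between 13096914 and 13142918 around unc-30 in any list, and the candidate upstream of unc-25 has a signal of 23.1 in the pooled list and 18.9 in replicate 1.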

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

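Both tests in this part were chosen after the result was seen. Replicate 2's ce11 list of candidate regions held 10 regions on the mitochondrial chromosome, a chromosome on which no thresholded peak lies. They stood out because replicate 1's list and the pooled list held 0. The highest had a signal value of 2497, against 55.8 for the highest nuclear region of that list, and 9 of the 10 lay above every nuclear region. All 10 were among the 125 highest regions of replicate 2. Without them, the shared part of the top regions was 24.0%, and replicate 2's top regions lay in promoters in 56.8% in place of 61.6%.

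More mitochondrial DNA in replicate 2, with equal processing of all lists, predicts mitochondrial regions in the pooled list, which was made from both libraries. That list held 0, although all 10 regions exceed its lowest signal of 10.7, if signal values may be set against each other across lists. This count is part of the pattern that was flagged and is no independent test. It argues against equal processing only on that condition, and only if the further file used with each replicate's alignments does not account for it. The latter could not be checked. Whether a filter on the mitochondrial chromosome was applied to some lists and not to others cannot be told, because the 10 regions in replicate 2's lists of both builds and their absence from both pooled lists are the pattern itself. The sources used here name no such filter, and whether replicate 2's library also held more mitochondrial DNA stays open. No biological explanation was tested.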

How the results depend on the processing

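Of the 88 alternative values of the main results, 62 were labelled unchanged. Tests so labelled kept their direction and side of the threshold, and shares stayed within their error. Counts stayed within a set ratio of the main count, such as 103 peaks against 125, or 47 to 92 6-mers against 63. The 62 included every test of the replicate overlap (whose share ran from 8.2% to 35.5%), the rank comparison and the count of gene lists. Alternatives with 500 or 1000 pooled regions, both-replicate peaks, nuclear regions of replicate 2 and whole lists were chosen after seeing the data. The causes of the changes below were not tested. The stricter list, the 62 peaks of higher signal, reversed the TAATCC difference (8.06% against 8.20% in flanks) and left 25 6-mers. The 33 peaks matched in both replicates reversed it too (6.06% against 7.58%), left 1 6-mer and ended the promoter call (48.5%). TAATCC passed its test at 14% in the looser list of 250, 14.2% in 500 and 11.5% in 1000 pooled regions, at 10.4% within 50 bp, and at 12.8% against shuffled windows (Fisher's exact test, p = 0.0368), and its p ran from 2.43e-05 to 1 over all alternatives. The 1250 shuffled windows were made from the same 125 peak windows, so they are not independent, which the exact test ignores. Without replicate 1 the TAATCC difference was gone, at 6.96% in regions and in flanks (exact p = 1), as good as gone in replicate 2's nuclear regions (7.2% against 6.85%, exact p = 1), and without replicate 2 it was 13.6% against 7.32% (exact p = 0.0604). In the same order, without replicate 1 or replicate 2, the 6-mers numbered 2 and 84, and the chromosomes past the threshold 0 and 1. 6-mers numbered 0 in replicate 2's nuclear regions, 41 within 50 bp and 98 in 1000 regions. Chromosomes past the threshold numbered 1 in 500 regions (V) and 2 in 1000 (III and V). Replicate support at both was 19.2% within 50 bp. With 250 regions per replicate it was 36.8% at both, 85.6% in replicate 1 and 46.4% in replicate 2, and with whole lists 81.6%, 96.0% and 84.8%. Of values for single lists, 166 kept their direction and 14 did not, where 0, 1 or 2 homeobox, pan-neuronal, D-type, neuropeptide or body wall muscle genes had a peak and none passed. Ranking by −log10 IDR was not run, because no list holds it. No paired analysis was possible because there is 1 group. Depth is unknown, so how far it limits replicate 2's peaks cannot be stated. The highest −log10 q of replicate 2's ce11 list was 0.635, a q-value above 0.05, so values from that list alone rest on uncertain regions.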

Other observations

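No comparison in this part was among the main tests fixed before the data were examined. For repeated sequence, the transgene's signal and the CGCAGGGA core, the prediction was written before the test was run. The gap around unc-30 and the X peaks far from gene starts had been seen by then. The other comparisons were chosen after the data were seen. The 16 thresholded peaks with TAATCC lay mainly away from promoters. Of the 47 peaks outside promoters, 13 held the motif (27.7%, interval 16.9 to 41.8), against 3 of the 78 promoter peaks (3.85%, interval 1.32 to 10.7; Fisher's exact test, two-sided, p = 0.000189). Against their own flanks the distal peaks also differed (5 of 92 windows, 5.43%, exact test, p = 0.000746), while 8.33% of the flanks of the promoter peaks held it (p = 0.275). Of the 13 distal peaks with the motif, those near T03G6.1, nspb-12, unc-60, C18G1.1 and msp-55 ranked 33 to 192 in replicate 2's list. The others ranked 573 to 14254 there or had no region. In replicate 1's list all but that near msp-55 had a region, with ranks of 16 to 1729. Of the 33 peaks matched in both replicates, 2 held the motif. The distal excess therefore rests more on replicate 1, and it was not tested in either replicate's own list. Over the 500 highest-signal pooled regions the shares were 20.1% outside and 9.61% inside promoters (exact test, p = 0.00115). Among these distal peaks was that of rank 105 at 11137707 to 11138062 of chromosome X, 12265 bp upstream of alr-1, a homeobox gene of the D-type list, with TAATCC at 11137966 to 11137971. Below the threshold, ttr-39 of the D-type list had a candidate (IV, 10089823 to 10090178, summit 124 bp upstream, pooled rank 651) with TAATCC at 10089928 to 10089933 and again at 10089939 to 10089944. It ranked 330 in replicate 1 and 29061 in replicate 2. unc-64 had its candidate 1488 bp upstream (pooled rank 204), with ranks of 931 and 155.

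Promoter peaks were also seen at genes of the mitochondrial ribosome and of chaperones, and other peaks lay near small nuclear RNA genes. These groups were picked because their genes had been seen among the same 125 peaks, so the counts describe these peaks and no test of them is given. Mitochondrial ribosomal protein genes had 4 of 66 members with a promoter peak (mrpl-28, mrpl-45, mrpl-48 and mrpl-55), and chaperone genes 5 of 59 (cct-1, cct-8, dnj-9, dnj-13 and hsp-60), against 0.653% and 0.647% of other genes. Of the other lists made after the peaks were seen, proteasome subunits had 1 of 33, translation initiation factors 1 of 31 and chemoreceptors 3 of 1171. Among the 9 mitochondrial ribosome and chaperone peaks only that of hsp-60 was in replicate 2's top 125 regions (rank 41). The others ranked 274 to 21250 there, or had no region (dnj-9), so the counts rest mainly on replicate 1. Small nuclear RNA genes lay within 300 bp of 4 summits (3.2%), against 0.0837% of the other candidates. They included 3 of the 18 sls-2 genes, which encode the SL2 spliced leader used for downstream genes of operons: sls-2.1 (rank 21), sls-2.2 (rank 38) and sls-2.4 (rank 68).

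Peaks on X differed from autosomal peaks in sequence and place. Of the 22 X peaks, 13 (59.1%) lay over 2000 bp from the nearest 5′ end, against 24 of 103 autosomal peaks (23.3%, Fisher's exact test, p = 0.00165). Candidate regions on X and on autosomes were not compared in this way, so whether the distance is particular to the peaks was not tested. The sequence CGCAGGGA, a core of the motif at recruitment sites of the dosage compensation complex on X, was in 9 of the 22 X peaks (40.9%, interval 23.3 to 61.3) and 0 of the 103 autosomal peaks (Fisher's exact test, p = 3.25e-08). Base composition alone is argued against, since 1 of 220 X candidates of matched G+C content held the core (exact test, p = 7.00e-10). The core was in 10 of 24 X regions among replicate 1's top 125 and 7 of 26 among replicate 2's, and it was in the peaks near W02H3.3, Y41G9A.17, cest-16, xol-1 and nspc-17. The hypothesis is that part of the strongest X peaks may be dosage compensation recruitment sites; whether tagged UNC-30 binds there, or such sites are recovered with any tagged protein, was not tested, since no other ChIP or control track was analysed here.

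The gap without candidates around unc-30 was 51327 bp long in the pooled list, 58900 bp in replicate 1 and 46005 bp in replicate 2, against a median gap of 1700 bp in the pooled list, and it was in the ce10 lists as well. Extra copies that raise the signal around unc-30 and unc-119 predict mean signals above percentile 95 of random windows at both, in each replicate. This was not met, but it cannot decide the question. The 40 kb around unc-30 held 0 candidates and so had no mean signal, and this gap had been seen before. The mean signal in the 40 kb around unc-119 was at percentile 61.3 in replicate 1 and 96.5 in replicate 2, so the replicates differ there. Other values at unc-119 go with extra copies there: its 40 kb held 20 candidates in each replicate against a median of 12 (96.45% and 96.9% of random windows held as few). The highest candidates within 2000 bp of the gene ranked 96 in replicate 1 and 95 in replicate 2. They lay at different sites, 10903512 and 10905852, and the promoter candidates ranked 24989 and 14919. Extra copies therefore stay open, at unc-119 alone or at both genes. Whether reads from the transgene's copies were removed through the control or the peak caller cannot be told: gaps at least as long held at most 0.987% of the nuclear genome in any list, which describes the gap again and decides nothing. Repeated sequence also remains open: 69.5% of the gap's 31-base words occur once in the genome, below the 5th percentile of random windows of its length (75.7%). Of 1000 random windows, 5 held no pooled candidate, and 4 of these were among the 28 with as low a share. The other windows of low uniqueness held candidates, so low uniqueness alone does not empty a window. No biological explanation was tested.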
